A study of Danio rerio with 3 samples.

How the data were processed

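Single cells were sorted from the trunk of zebrafish embryos at 36 hours post fertilization and their transcripts were sequenced by STRT-seq, a plate-based single-cell method. The fish carried a GFP reporter driven by spi2 and an mCherry reporter driven by kdrl. The deposited cell table lists the DP libraries as kdrl+spi2+ cells and the SP library as kdrl-spi2+ cells. Per the labels' protocols, the libraries were made with KAPA Hyper Prep chemistry and sequenced as 150 bp paired-end reads on a NovaSeq instrument. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0 and the genome build GRCz11 were used. Those notes cover several assays and do not say which tool served which.

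The deposited table holds whole-number counts per gene and cell, which were used as the authors gave them. The counting tool, whether identical molecules were collapsed, the use of strand and any filter on cells are not given in the sources used here. Of the nonzero entries 19.7% were 1, their median was 8, their mean was 44.1 and the highest was 18978. The table names 19831 genes by symbol, of which 15289 had a count and 14456 matched the Ensembl name table. Near-identical copies, such as hsp70.1, hsp70.2 and hsp70.3 or the embryonic globins, may share counts in ways that cannot be traced here. No coordinates are reported.

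The count table holds 56 cells of DP 1 and 37 of DP 2. The cell table lists 55 cells of DP 1, 93 of DP 2 and 93 of SP 1. The 93 SP cells and 56 of the listed DP 2 cells were not analysed here, and 1 DP 1 well with counts is absent from the cell table. The comparison of DP with SP cells, by genes and by lists, had been planned before the data were examined and was therefore not run. The gene lists, the filter on cells, the clustering settings, the rule for named genes and the test were also fixed before the data were examined. The marker classes and the tests between them were chosen after the data were seen, to use the replicated libraries that could be compared. The choice of genes and lists between DP 1 and DP 2 was also made after the data were seen.

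Cells with 500 or more detected genes were kept, which left 88 cells (53 of DP 1 and 35 of DP 2) and removed 5. No doublet caller was run on cells sorted singly, and 0 cells met both marker class definitions. No 2 cells had identical counts. Shares of cells are given with exact Clopper-Pearson 95% intervals and summed counts with exact Poisson 95% intervals. Both kinds of interval cover counting error only, since counts may not be independent molecules. To compare shares across depths, each cell was thinned to 20217 counts, the 10th percentile of totals, which leaves out 9 shallower cells (3 of DP 1 and 6 of DP 2) and keeps 79.

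Cells were clustered with scanpy 1.11.5, anndata 0.12.19 and leidenalg 0.10.2 on log-normalised counts (10000 per cell), 2000 variable genes, 15 principal components, 10 neighbours, resolution 1.0 and seed 0, using genes found in at least 3 cells. A cluster was named for the type with the most passing markers fixed in advance, with at least 3 needed. A marker passed if it was found in at least 50% of the cluster's cells and was at least 4-fold higher than in the other cells. A cluster stayed unnamed if another type had more markers among its 10 leading genes. It also stayed unnamed if its cells had low totals and no own marker was among those 10. Because the clusters rest on the same genes that would be tested, clustering without the genes of the tested lists was tried first. It no longer separated the endothelial-like cluster and was dropped. Classes were then defined from the number of fixed markers found in thinned counts, and both minimums were placed at gaps seen in those numbers, so the class tests are exploratory. Endothelial-marker cells had at least 6 of 20 pan-endothelial markers, neutrophil-marker cells had at least 7 of 12 neutrophil markers, and the rest had neither.

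Raw counts were summed per library and class, which gave 6 sums. They were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr and the quasi-likelihood test, two-sided, with library as a block, class as the factor and 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The markers that define the classes were left out, which left 6713 tested genes. Each marker class was compared with the cells of neither class. Fold changes are as fitted, and the median over all tested genes was -0.20 for the endothelial-marker class and -0.23 for the neutrophil-marker class. Each SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F, not the error of a fitted coefficient. With DESeq2 size factors these medians were 0.03 and -0.20.

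Of the 26 gene lists, 17 had at least 3 tested genes and did not define a class. They were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 17 lists per contrast. Camera with an estimated correlation and fry were the alternatives. The macrophage, thrombocyte, neural, epidermal, mesenchymal, neural crest and pigment, and antiviral interferon lists had too few tested genes. Between DP 1 and DP 2, with 1 library each, no test was made. A list's median log2 ratio was placed among those of 10000 random lists of the same size matched on expression. These ratios used summed CPM plus a pseudocount of 1. Tests of explanations in the closing section were revised after earlier forms had been seen. The share of cells with a muscle count reached 100% in every class of DP 2 and could decide nothing, and equal levels between classes would also follow from other sources, so counts per cell were compared between deeper and shallower cells. The share of lyz counts in the 3 highest cells of neither class was 73.0% in DP 1 and 93.3% in DP 2, although 92.9% and 63.6% of thinned cells held lyz, which left that test undecided, so npsn was compared with lyz, first against the summed neutrophil-marker cells and then against each of them. The test of carry-over at low level first used 5 of the 7 neutrophil genes and then all 7.

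Named genes were the sort genes kdrl and spi2 with the hemogenic genes runx1, myb, gata2b and gfi1aa. To these the rule added the 12 genes with the largest fold change in each direction among those called and in the same direction in both libraries, or those with the smallest p where fewer than 12 passed, without clone-type symbols. Up to 4 members per list with the highest level and up to 4 with the smallest p completed the rule. Between DP 1 and DP 2, the 12 largest ratios in each direction were named among genes with a mean of 100 CPM or more that were found in at least 50% of cells of the higher library. Against a class with 0 counts a fold is a lower bound set at 3 counts over the class, and with 1 to 3 counts it is the ratio of summed counts with its exact interval.

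The class test was checked on simulated counts for 6737 genes of the neutrophil-marker comparison, with 200 genes changed, in 3 simulations. It recovered 0.667% of genes changed 4-fold, 10.7% of those changed 16-fold and 35.0% of those changed 64-fold, with a mean of 0.667 false calls and 0 calls of the wrong sign. Among unchanged genes 8.79% had an unadjusted p under 0.05, above the nominal 5%. An earlier form of that simulation, with trended dispersions and smaller folds, recovered almost no gene. The percentile placement was checked on 50 lists of 15 genes drawn at random from the real ratios of DP 2 to DP 1. With 1 added on the log2 scale, 47 of 50 lay above the central 95% of random lists. Unshifted, 1 of 50 lay outside the central range. Since these genes were drawn at random, the check does not cover lists whose members vary together. Alternatives covered the scaling, the count filter, the quasi-likelihood settings, the DESeq2 1.42.0 Wald test, thinning, other marker numbers, a higher gene minimum, leaving out the deepest cell of each class in each library, leaving out a library, and other cluster settings. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.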

Results

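The data are single-cell transcript counts from 2 libraries of DP cells, sorted as positive for both the kdrl and the spi2 reporter from zebrafish trunks at 36 hours post fertilization. At this stage hemogenic endothelium of the dorsal aorta gives rise to blood stem and progenitor cells, and the series asks how lineage competence arises there. DP 1 gave 53 kept cells with 9232289 counts in all, and DP 2 gave 35 kept cells with 3114643. Totals per cell ran from 15439 to 903548 in DP 1 (median 134394) and from 4818 to 379006 in DP 2 (median 58292). The median number of genes per cell was 3543 in DP 1 and 2695 in DP 2. The SP library, sorted as kdrl-spi2+, was not analysed here, so no comparison of DP with SP cells was made. The labels do not say that the libraries came from separate groups of embryos. With library as a block, the p-values below set class differences only against their variation between these libraries, which may be technical.

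The sort gene spi2, which encodes an ETS-family transcription factor, was found in 84.9% of DP 1 cells (45 of 53, interval 72.4 to 93.3) and 85.7% of DP 2 cells (30 of 35, interval 69.7 to 95.2). Transcripts of kdrl, the gene of an endothelial VEGF receptor, were found in 28.3% of DP 1 cells (15 of 53, interval 16.8 to 42.3) and 42.9% of DP 2 cells (15 of 35, interval 26.3 to 60.6). All 15 kdrl-positive cells of each library also held spi2 transcripts. The hemogenic regulator runx1 was found in 13.2% of DP 1 cells (interval 5.48 to 25.3) and 8.57% of DP 2 cells (interval 1.80 to 23.1), while myb, a regulator of blood stem cells, was found in 90.6% and 85.7%. The hemogenic transcription factor genes gata2b and gfi1aa were found in 7.55% and 32.1% of DP 1 cells and in 22.9% and 11.4% of DP 2 cells.

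In cells thinned to equal depth, kdrl was left in 4.0% of DP 1 cells and 31.0% of DP 2 cells, and spi2 in 68.0% and 82.8%. The thinned shares were 8.0% and 10.3% for runx1, 92.0% and 79.3% for myb, 4.0% and 20.7% for gata2b, and 18% and 6.90% for gfi1aa. The summed level of kdrl was 4.01 CPM in DP 1 (interval 2.82 to 5.52) and 40.5 CPM in DP 2 (interval 33.7 to 48.2), and that of spi2 was 247 CPM (interval 237 to 257) and 345 CPM (interval 325 to 367). For myb the levels were 322 and 127 CPM, for gata2b 5.2 and 35.3, for gfi1aa 30.3 and 11.2, and for runx1 8.45 and 6.42. Both libraries carry the label kdrl+spi2+, which does not say that the sort gates were equal. With 1 library on each side these values carry no replicate check.

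The kept cells formed 6 clusters, of which 2 could be named from fixed markers. An endothelial-like cluster of 12 cells (5 of DP 1 and 7 of DP 2) held 10 endothelial markers, among them cdh5, pecam1, dll4, efnb2a, sox7 and kdrl. A myeloid-like cluster of 10 cells (7 and 3) held 20 myeloid markers. Its leading genes included npsn, mpx, mmp13a and cpa5 of the fixed neutrophil list and the lysosomal phosphatase gene acp5a. The other 66 cells fell into 4 unnamed clusters of 20, 19, 18 and 9 cells. The 3 largest of these held 19, 17 and 17 cells of 1 library, so that each may be that library and not a cell type. The 19-cell cluster, with 17 cells of DP 2, was led by cd59, csf3b and hsp70.1. Endothelial-like cells made up 9.43% of DP 1 (interval 3.13 to 20.7) and 20% of DP 2 (interval 8.44 to 36.9), and myeloid-like cells 13.2% (interval 5.48 to 25.3) and 8.57% (interval 1.80 to 23.1). At resolution 0.5 no cluster held enough endothelial markers for the name. With 1000 variable genes a cluster of 12 cells (3 of DP 1 and 9 of DP 2) still held 9 endothelial markers. It stayed unnamed because its 10 leading genes included 1 marker of another type and 0 endothelial markers. In both settings 0 cells carried the name.

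Marker classes set on thinned counts gave 8 endothelial-marker cells (3 of DP 1 and 5 of DP 2), 7 neutrophil-marker cells (5 and 2) and 64 cells of neither class (42 and 22). The shares were 6.0% of thinned DP 1 cells (interval 1.25 to 16.5) and 17.2% of DP 2 cells (interval 5.85 to 35.8) for the endothelial-marker class. For the neutrophil-marker class they were 10.0% (interval 3.33 to 21.8) and 6.90% (interval 0.846 to 22.8). All 8 endothelial-marker cells lay in the endothelial-like cluster and all 7 neutrophil-marker cells in the myeloid-like cluster. No cell sat exactly at either minimum, 6 cells lay 1 or 2 endothelial markers below it and 4 cells lay 1 neutrophil marker below it. The median endothelial-marker cell held 5 neutrophil markers in DP 1 and 2 in DP 2, and the median neutrophil-marker cell held 2 and 1.5 endothelial markers. The classes are ranges of a marker number, and their sums rest on few cells: the deepest endothelial-marker cell gave 49.7% of its sum in DP 1 and 47.1% in DP 2, and the deepest neutrophil-marker cell 29.6% and 70.0%.

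The sort gene spi2 was at 1590 CPM in the endothelial-marker cells of DP 1 against 183 CPM in cells of neither class, and at 378 CPM in both classes of DP 2. In neutrophil-marker cells it was at 5.04 CPM in DP 1 and had 0 of 206670 counts in DP 2, which allows up to 14.5 CPM. The gene gfi1aa was at 300 and 26.1 CPM in endothelial-marker cells of DP 1 and DP 2, against 14.3 and 6.88 CPM in cells of neither class. Levels of gata2b were 13.6 and 111 CPM in endothelial-marker cells against 5.41 and 8.36 CPM. Levels of myb were 257 and 82.0 CPM against 341 and 142 CPM in cells of neither class. Counts of runx1 were too few for a class comparison, with 0 in DP 1 and 7 in DP 2 endothelial-marker cells.

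**Figure D1:**
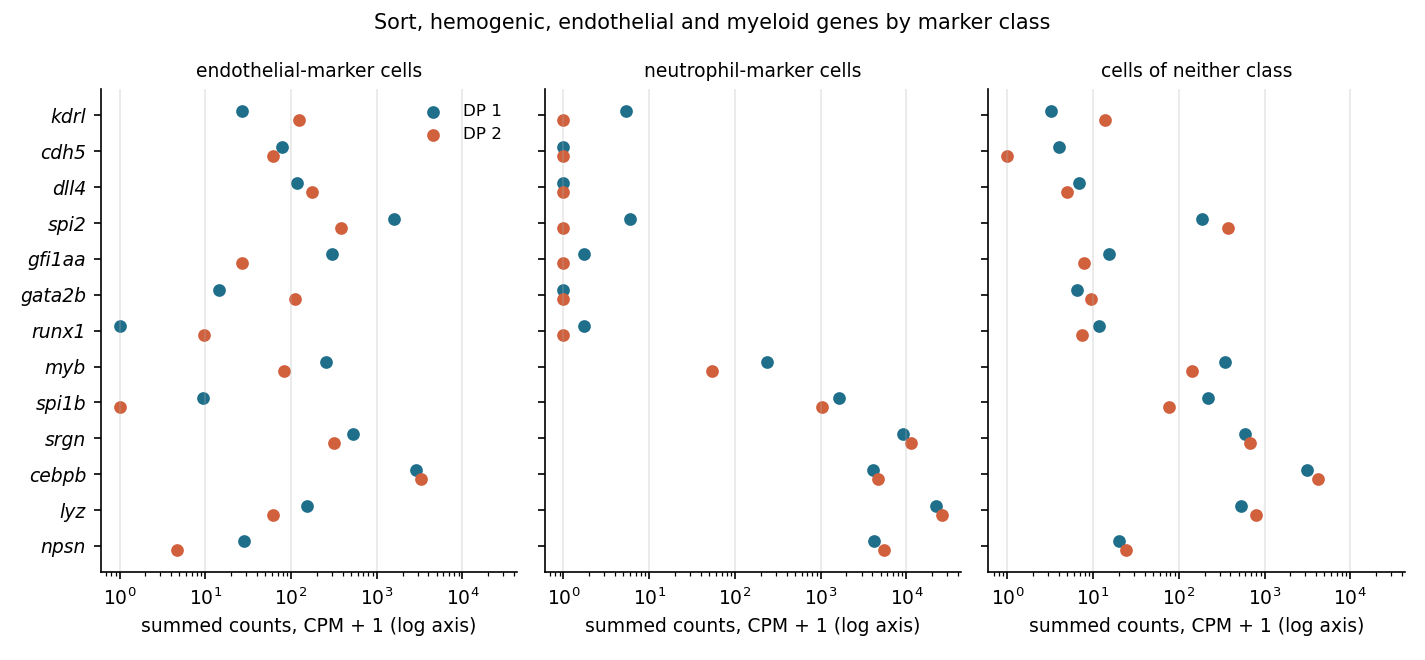
Summed level of each gene (CPM plus 1, log axis) in endothelial-marker cells, neutrophil-marker cells and cells of neither class, with 1 point per library. Points for spi2 lie at 1590 and 378 CPM in endothelial-marker cells and at 5.04 CPM or 0 in neutrophil-marker cells, while myb is found in all 3 groups.

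The genes with the largest rises in endothelial-marker cells over cells of neither class are given first, and no test was made of what they share. The caveolar coat gene cavin1b was at least 246-fold higher, with 111 counts against 0. The caveolin gene cav1 was higher by 7.12 ± 1.08 (log2 ± SE, n = 2 libraries) and cavin2b by 6.89 ± 0.90 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0131 and 0.0058). The aquaporin gene aqp8a.1 was 737-fold higher by summed counts (interval 250 to 3590, 333 against 3 counts), and aqp1a.1 was higher by 7.30 ± 1.15. The collagen gene col4a2 was 411-fold higher (interval 112 to 3435), and its partner col4a1 was higher by 6.84 ± 1.25. The sizes differed between the libraries, with log2 differences in DP 1 and DP 2 of 8.29 and 5.34 for aqp8a.1, 7.77 and 3.24 for aqp1a.1, and 6.60 and 3.36 for col4a1, and 101 of the 111 cavin1b counts came from DP 1.

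The other genes with the largest rises were tnfaip2b (7.69 ± 0.95), fhl2a (6.80 ± 1.23) and the semaphorin gene sema5a (6.67 ± 1.17), with gstt1b at 763-fold (interval 134 to 30399) and cdc42ep5 at 610-fold (interval 107 to 24371) by summed counts. Counts of cdc42ep5 were 53 against 0 in DP 1 and 39 against 1 in DP 2, so the pooled ratio rests on 1 count. Among fixed markers of other cell types, the keratin gene krt8 rose by 5.09 ± 0.52 and the matrix gene postnb by 5.24 ± 0.89 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0006 and 0.0193). The 8 genes that fell included spi1b, which encodes the myeloid transcription factor PU.1, at -5.37 ± 0.93 (5 counts against 1707), and the chemokine receptor gene cxcr4b at -2.24 ± 0.44. The profilin gene pfn1 (-2.0 ± 0.28), the spermine synthase gene sms (-4.13 ± 0.65), papss2b (-4.92 ± 0.79), gpr183a (-5.00 ± 0.98), nccrp1 (-2.97 ± 0.55) and blf (-2.80 ± 0.53) fell as well. For blf the log2 differences were -3.74 in DP 1 and -1.95 in DP 2. The next by unadjusted p were antxr2a at -3.77, laptm5 at -3.56, mrpl52 at -3.92 and fabp3 at -4.13, and none of these passed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 0.0518 to 0.0634).

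Of 6713 genes tested, 57 were higher and 8 lower in endothelial-marker cells at the adjusted threshold, and 519 and 341 had an unadjusted p under 0.05. All 65 went in the same direction in both libraries. The blocked test takes disagreement between the libraries as its error, so this shared direction is not independent support. The count was 19 with the deepest cell of each class in each library left out, 28 with lower marker minimums, 120 with robust fitting and 137 without the library block. With the legacy quasi-likelihood method 17 genes were higher and 28 lower.

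Among hemogenic genes, gfi1aa was at 3.73 ± 0.85, gata2b at 2.65 ± 0.97, spi2 at 1.45 ± 0.68 and myb at -0.75 ± 0.52, and none passed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0639, 0.283, 0.390 and 0.553). The value of spi2 rests on DP 1, since it was -0.16 without that library. As a list, hemogenic and stem/progenitor genes lay above the other genes (camera, Benjamini-Hochberg adjusted p = 0.00207, 8 genes), and adjusted over the list alone 1 of them passed. In the 2 libraries 4 of the 8 went in opposite directions. Its adjusted p = 0.185 with an estimated correlation.

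As a list, arterial genes lay above the other genes in endothelial-marker cells (camera, Benjamini-Hochberg adjusted p = 7.79e-06, and adjusted p = 0.185 with an estimated correlation). This is a list of endothelial markers, as are the markers that define the class, so its rise is not an independent finding. Of 6 tested, 3 rose, namely aqp8a.1, the Notch ligand gene dll4 (4.51 ± 0.80) and the ephrin gene efnb2a (5.01 ± 1.01), and adjusted over the list alone 4 rose. In opposite directions in the libraries went 2 of the 6, such as cxcr4a at -2.30 in DP 1 and 3.13 in DP 2. Basement membrane genes (2 of 5 called, 4 adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 1.37e-05) lay above the rest, with col4a1 and col4a2 called and the laminin gene lama4 at 4.19 ± 1.12. The Notch list (1 of 11 called, 4 adjusted over the list alone, camera with Benjamini-Hochberg adjusted p = 0.000108) lay above the rest too, with dll4 called, 4 of 11 in opposite directions in the libraries and the Notch target gene her15.1 at 6.59 ± 1.58. Both lists had an adjusted p = 0.185 with an estimated correlation, and the values of lama4 and her15.1 did not pass the gene test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.110 and 0.0846).

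Genes of the shear stress and BMP response (camera, Benjamini-Hochberg adjusted p = 0.000275) and of cell junctions (0.000352) also lay above the rest, each with an adjusted p = 0.185 with an estimated correlation. In the first list the BMP target gene id1 rose by 4.29 ± 0.72, 1 of 6 called and 3 adjusted over the list alone, while the flow-responsive genes klf2a (4.24 ± 0.97) and klf2b (3.68 ± 0.93) missed the threshold. Other members, id3 at 0.0010 and id2a at -0.00069, lay near 0, and 3 of the 6 went in opposite directions in the libraries, with medians of 2.36 in DP 1 and 0.64 in DP 2. In the junction list 0 of 9 genes were called, 4 adjusted over the list alone and 2 went in opposite directions, with afdna at 4.36 ± 1.12 and ctnna1 at 3.27 ± 0.95. The immediate early and heat shock list lay above the rest too (camera, Benjamini-Hochberg adjusted p = 3.0e-07, and adjusted p = 0.185 with an estimated correlation). Its called member was atf3 (3.38 ± 0.47), 1 of 21, and adjusted over the list alone 7 rose. Against cells of neither class, all 4 heat shock members were higher in endothelial-marker cells of DP 1 and lower in those of DP 2, such as hsp70.2 at 674 against 41.4 CPM and at 140 against 965 CPM, while 15 of 17 immediate early members went the same way in both libraries. This list marks handling stress as well as signalling.

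As a list, pan-myeloid genes lay below the other genes (camera, Benjamini-Hochberg adjusted p = 4.49e-05, and adjusted p = 0.185 with an estimated correlation). Of 15 tested, 1 was called, spi1b, and adjusted over the list alone 4 fell, while cebpa was at 0.02 and the granule proteoglycan gene srgn at -0.78. Ribosomal protein genes lay slightly below the other genes, with a median of -0.28 that is -0.08 from the median of all genes, and 0 of 80 were called. Their camera adjusted p (Benjamini-Hochberg) was 1.71e-05, but the adjusted p = 0.828 with an estimated correlation, and it was 0.567 with DESeq2 size factors.

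The other lists were not called by camera with Benjamini-Hochberg adjustment in the reported fit. The adjusted p was 0.121 for G2/M phase, 0.149 for erythroid, 0.243 for mitochondrially encoded, 0.596 for venous and lymphatic, 0.671 for S phase, 0.792 for lymphoid and for skeletal muscle, and 0.943 for inflammatory genes. G2/M genes were called lower without the deepest cell (0.00122) and with no count filter (0.0234), and mitochondrially encoded genes in thinned cells (0.000316) and with no count filter (0.000106). None of these calls passed with an estimated correlation in the same setting (adjusted p from 0.460 to 0.619). For skeletal muscle the median was -0.55 although camera placed the list above the rest. For inflammatory genes the median was 0.0093 and the mean -0.14.

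Neutrophil-marker cells had higher levels of further myeloid genes and far lower levels of spi2. The granule proteoglycan gene srgn rose by 4.08 ± 0.34 and spi1b by 3.40 ± 0.45 (log2 ± SE, n = 2 libraries, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0003 and 0.0021). The Fc receptor gamma gene fcer1gl rose by 4.92 ± 0.58, the NADPH oxidase gene cyba by 3.70 ± 0.65, the cathepsin gene ctss2.1 by 6.61 ± 0.86 and the cytokine gene il1b by 4.45 ± 0.66. The gene spi2 fell by 5.99 on the log2 scale (SE 1.29, adjusted p = 0.0423 by the same test), with 7 and 0 counts in neutrophil-marker cells of DP 1 and DP 2 against 1319 and 768 in cells of neither class. For myb the value was -0.54 ± 0.55 and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.702).

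The largest rises by the naming rule were the lipoxygenase gene alox12, 347-fold by summed counts (interval 117 to 1701, 180 against 3 counts), the fatty acid binding protein gene fabp7a (7.66 ± 1.32), the retinol dehydrogenase gene rdh12l (6.97 ± 1.42), thy1 (6.96 ± 1.15) and cited2 (6.21 ± 0.99). The cytokine signalling inhibitor gene socs1a (6.19 ± 1.23), gpd1c (5.43 ± 1.07), nucb2b (5.32 ± 1.05), aldh8a1 (5.17 ± 0.67) and the elongase gene elovl1b (4.93 ± 0.70) followed. Counts of fabp7a and nucb2b came almost all from DP 1, with 173 and 178 there against 2 and 2 in DP 2, as did 168 of the 180 alox12 counts. The log2 differences in DP 1 and DP 2 were 6.73 and 2.59 for socs1a and 5.95 and 3.12 for gpd1c. After spi2, the largest falls were in pmp22b (-5.33 ± 0.67), the chromatin gene hmgb3a (-5.30 ± 1.12), znfl2a (-5.00 ± 0.97), tspan36 (-4.31 ± 0.81), blf (-4.13 ± 0.63) and igfbp1a (-4.10 ± 0.78). The chaperone gene hsp90aa1.2 (-3.85 ± 0.69), the syndecan gene sdc4 (-3.82 ± 0.87), inka1b (-3.33 ± 0.72), the DNA methyltransferase gene dnmt3ba (-2.97 ± 0.66) and stmn1a (-2.74 ± 0.54) fell as well. For hsp90aa1.2 and dnmt3ba the log2 differences were -2.43 and -2.56 in DP 1 and -6.30 and -5.58 in DP 2.

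**Figure D2:**
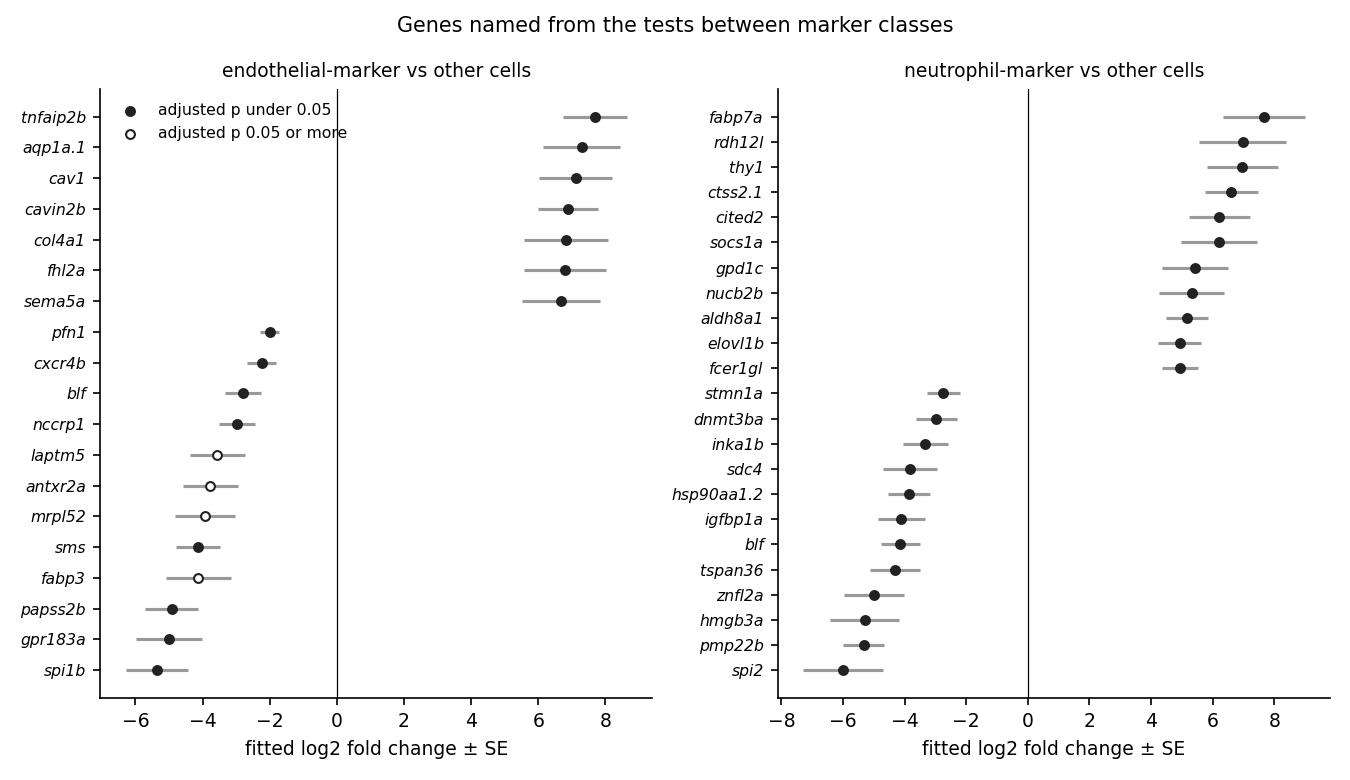
Fitted log2 fold change with the SE derived from the quasi-likelihood F (bars) for genes named from the tests of endothelial-marker and neutrophil-marker cells against cells of neither class, n = 2 libraries. Filled points passed an adjusted p of 0.05 and open points did not; spi1b lies at -5.37 in the first panel and spi2 at -5.99 in the second.

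In all, 79 genes were higher and 16 lower in neutrophil-marker cells (edgeR quasi-likelihood, 6713 genes). All 95 went the same way in both libraries, which the blocked test favours by its design. At an unadjusted p under 0.05 the counts were 501 and 368. With the deepest cell of each class in each library left out 33 genes were called, and with robust fitting 150. With cells thinned to equal depth, where only 1653 genes were tested, 145 were higher and 75 lower.

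As a list, pan-myeloid genes lay above the other genes in these cells (camera, Benjamini-Hochberg adjusted p = 1.45e-35, and adjusted p = 0.129 with an estimated correlation). Of 15 tested, 6 rose and 14 rose adjusted over the list alone, while the myeloid transcription factor gene cebpb was at 0.35 ± 0.29. This list is a marker list of the same lineage as the markers that define the class. The immediate early and heat shock list lay below the rest (camera, Benjamini-Hochberg adjusted p = 4.53e-07, and adjusted p = 0.735 with an estimated correlation), with 18 of 21 negative, 2 called, junbb (-2.22 ± 0.39) and btg2 (-2.54 ± 0.53), and 12 adjusted over the list alone. S phase genes lay below the rest, with all 18 fitted values negative (camera, Benjamini-Hochberg adjusted p = 0.0383, and adjusted p = 0.944 with an estimated correlation). In DP 1 alone 4 of the 18 were positive, and the list median was -0.57 there and -2.70 in DP 2, where the class is 2 cells. None of them was called, and the helicase genes mcm6 and mcm7 were at -2.37 ± 0.65 and -1.99 ± 0.65.

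The remaining lists were not called by camera with Benjamini-Hochberg adjustment in the reported fit. The adjusted p was 0.0667 for hemogenic genes, of which spi2 alone was called, 0.145 for venous and lymphatic, 0.324 for lymphoid and for ribosomal, 0.439 for junction and for erythroid, and 0.700 for G2/M genes. For inflammatory, muscle, shear stress and BMP, mitochondrially encoded, arterial and basement membrane genes it was 0.894, and for Notch genes 0.935. Ribosomal genes were called higher with DESeq2 size factors (5.28e-05) but lower with no count filter (0.00167), and hemogenic genes were called lower with looser marker numbers (0.0124) and with no count filter (0.00066). G2/M genes were called higher with looser marker numbers (0.0212). Mitochondrially encoded genes were called lower in thinned cells (1.02e-05) and with no count filter (0.0233) but higher with looser marker numbers (0.0384). None of these calls passed with an estimated correlation in the same setting (adjusted p from 0.455 to 0.902), and 63 of 80 ribosomal, 12 of 18 G2/M and 11 of 13 mitochondrially encoded genes went in opposite directions in the libraries. The inflammatory list held 1 called gene, il1b. Ribosomal, muscle and inflammatory genes were placed above the rest by camera although the medians of the first and second lists were -0.05 and -0.13 and the mean of the third was -0.26. The difference between endothelial-marker and neutrophil-marker cells was not itself tested.

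The libraries DP 1 and DP 2 carry the same sorting label, and their comparison shows how far they differ. Summed over all cells, the heat shock genes below were higher in DP 2, where the chaperone gene hsp70.1 was at 439 CPM (interval 416 to 463) against 16.1 CPM in DP 1 (interval 13.7 to 18.9). The related hsp70.2 was at 691 against 75.4 CPM and hsp90aa1.2 at 1760 against 215 CPM. In endothelial-marker cells hsp70.2, hsp70.3 and hsp70l were lower in DP 2 (140, 128 and 295 CPM) than in DP 1 (674, 597 and 613 CPM). There hsp70.1 differed little (109 against 126 CPM) and hsp90aa1.2 was higher in DP 2 (1170 against 397 CPM). These sums rest on 3 cells of DP 1 and 5 of DP 2. The 3 cells ran from 9662 to 30701 CPM for the immediate early and heat shock list. Summed over all cells, the complement regulator gene cd59 was at 226 CPM in DP 2 against 6.50 CPM in DP 1. The gene csf3b of a granulocyte growth factor was at 365 against 32.6 CPM. Higher in DP 1 were the importin gene kpna2 at 792 against 174 CPM and the topoisomerase gene top2a at 162 against 41.1 CPM.

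The other genes picked by size in DP 2 were hsp70.3, hsp70l, cbx7a, brdt, the inhibitor gene nfkbiaa and the keratin genes krt18a.1 and krt8. The other genes picked by size in DP 1 were lsp1b, hist1h4l, il6r, sb:cb81, dusp2, arpc4, map2k6, eif2s1a, znfl2a and plek. Relative to the median gene, whose log2 ratio of DP 2 to DP 1 was -0.39, the DP 2 genes lay from 2.56 (brdt) to 5.31 (cd59) and the DP 1 genes from -1.79 (kpna2) to -1.41 (plek). With 1 library on each side there is no replicate check and no p-value.

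Across 7946 genes, which are not independent replicates, the log2 levels of DP 1 and DP 2 correlated with Pearson 0.871 and Spearman 0.804. Over 2-fold apart were 2706 genes (34.1%), 683 higher in DP 2 and 2023 higher in DP 1. Random splits of the DP 1 cells into parts of 26 gave a mean Pearson correlation of 0.838 (0.806 to 0.856 over 100 splits) and 32.1% of genes over 2-fold apart (29.8 to 37.3). Their mean Spearman correlation of 0.835 was above that of the libraries. The directions were about even, with means of 1251 and 1300 genes. Parts of 26 cells are smaller than the libraries of 53 and 35 cells. The splits therefore do not show that the libraries differ no more than cells of 1 library. Between the libraries, the count of genes over 2-fold apart was 1362 of 5035 (27.1%) with a stricter filter on counts and 949 of 3900 (24.3%) in thinned cells. For means over cells of CPM it was 3085 of 7946 (38.8%).

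Among the fixed lists, immediate early and heat shock genes and ribosomal protein genes lay at the 100th percentile of random lists in DP 2. The first had a median of 1.23 relative to the median gene, with all 21 members above it. For means over cells its unscaled median was 0.30, with the median gene at -0.42, beside 0.84 in the sums. Ribosomal protein genes took 40.8% of DP 2 counts and 30.9% of DP 1 counts, and 79 of 80 lay above the median gene. Pan-endothelial genes (percentile 99.9, relative median 1.08), arterial genes (99.8, 1.55), Notch genes (99.4, 0.88), inflammatory genes (99.8, 0.78), junction genes (98.0, 0.82) and basement membrane genes (97.6, 1.0) lay above most random lists. For means over cells the unscaled inflammatory median was -0.11 where the median gene was at -0.42, and in thinned cells the junction median was -0.0025 where the median gene was at -0.35. G2/M genes lay lowest, with a relative median of -1.19 and 16 of 18 below the median gene (percentile 0.00), and neutrophil genes (0.17, -0.80) and pan-myeloid genes (1.86, -0.49) followed. Endothelial-marker cells were 17.2% of thinned DP 2 cells and 6.0% of thinned DP 1 cells, and neutrophil-marker cells 6.90% and 10.0%. Sums over all cells do not separate such a mix from levels within cells, and this was not tested for these cell type lists. For means over cells the percentiles were 23.9 for neutrophil, 32.2 for pan-myeloid, 90.7 for inflammatory and 97.4 for junction genes. In thinned cells they were 13.1, 67.2, 92.9 and 65.3, and 96.5 for arterial genes.

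The percentiles of the other lists were 30.2 for venous and lymphatic, 62.6 for hemogenic, 52.3 for erythroid, 74.1 for lymphoid, 96.0 for neural, 71.0 for mesenchymal, 17.6 for S phase, 74.5 for antiviral interferon, 39.9 for shear stress and BMP, and 60.7 for mitochondrially encoded genes. Of these, hemogenic genes lay at 18.5 for means over cells and at 1.16 in thinned cells, mitochondrially encoded genes at 0.00 in thinned cells and neural genes at 99.9 for means over cells. Skeletal muscle, macrophage, epidermal, thrombocyte and neural crest lists had too few members at the level needed. Skeletal muscle transcripts nevertheless differed between the libraries, although single cells overlapped. A count of the muscle list was found in 100% of DP 2 cells (35 of 35) and 52.8% of DP 1 cells (28 of 53). The list reached 297 CPM in 1 DP 1 cell and was at 83.4 CPM in 1 DP 2 cell. The cardiac-type actin gene actc1b, also abundant in embryonic skeletal muscle, was found in 94.3% of DP 2 cells (33 of 35) and 17.0% of DP 1 cells (9 of 53). The median cell held 325 CPM of muscle list transcripts in DP 2 and 3.23 CPM in DP 1. Between endothelial-marker cells and cells of neither class the fold change of actc1b was -0.35 ± 0.86 and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.890).

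**Figure D3:**
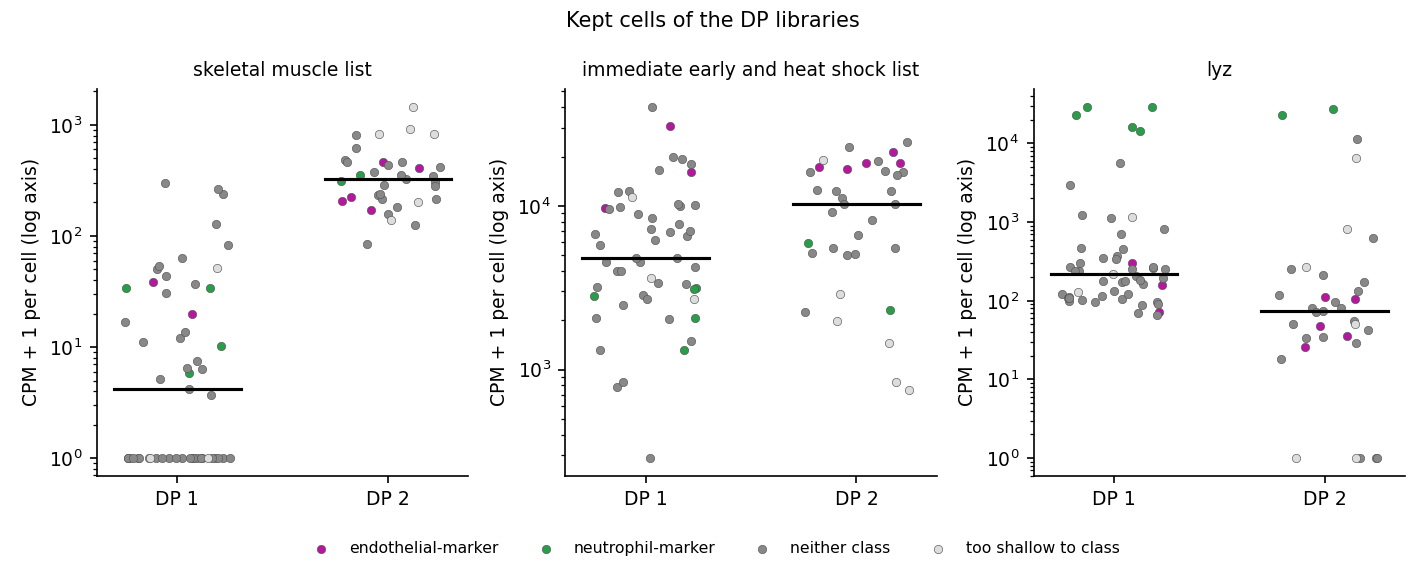
Level per kept cell (CPM plus 1, log axis) of the skeletal muscle list, the immediate early and heat shock list and lyz in DP 1 and DP 2, with points coloured by marker class and bars at the medians. Muscle transcripts have medians of 3.23 CPM in DP 1 and 325 CPM in DP 2. Medians of the immediate early and heat shock list, mostly immediate early transcripts, are 4827 and 10304 CPM.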

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

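All tests in this part were chosen after the results were seen. The wells with under 500 genes, 5 in all, entered no comparison of the report. The 3 left-out wells of DP 1 held 1009 counts, of which 24 were skeletal muscle counts (2.38%, interval 1.53 to 3.52), 4 were neutrophil counts and 9 were immediate early and heat shock counts. All 24 muscle counts came from the DP 1 well that is absent from the cell table, where they made up 12.6% of 191 counts (interval 8.22 to 18.1) and came from 10 muscle genes, with 9 counts of actc1b. Kept DP 1 cells held 0.00210% of their counts in muscle genes. The 2 left-out wells of DP 2 held 1360 counts, of which 24 were immediate early and heat shock counts (1.76%, interval 1.13 to 2.61), beside 1.35% in kept DP 2 cells. These wells also held 2 neutrophil counts and 0 muscle counts, which allows a muscle share of up to 0.271%, above the 0.0328% of kept DP 2 cells.

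Muscle transcripts were also spread over DP 2, where the muscle list had a median of 325 CPM per cell against 3.23 CPM in DP 1. A few muscle cells in the sort do not account for this, since the 3 highest cells held 27.0% of the DP 2 muscle counts. Depth does not account for it either, since 100% of thinned DP 2 cells (29 of 29, interval 88.1 to 100) held a muscle count against 22.0% in DP 1 (interval 11.5 to 36.0), although DP 2 was the shallower library. Muscle RNA from outside the cells stays open: a like amount in every well would give like counts, but deeper DP 2 cells held 3.93 times the muscle counts of shallower ones (interval 3.36 to 4.61) at 4.52 times the mean total, and a total that follows the capture of RNA in the well would give this too. The summed level of 277, 324 and 334 CPM in the marker classes does not decide it, and no biological explanation was tested, since the design gives none between libraries of 1 group.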

How the results depend on the processing

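The alternatives for shares of cells, clusters and the agreement of the libraries were planned, and those for marker classes and for lists between libraries were chosen after the data were seen. The planned comparison of DP with SP cells, by genes and by lists, was not run with any alternative. No paired analysis was possible because DP and SP share only 1 replicate number and SP cells were not analysed here. Where no cause is given below, the cause was not tested.

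The share of DP 1 cells with kdrl was 4.0% in thinned cells and 15.09% at 2 or more counts, that with spi2 was 68.0% in thinned cells, and that with gfi1aa was 18% and 17.0%. The share of DP 2 cells with spi2 was 68.6% at 2 or more counts. Fewer counts per cell lower such shares by construction. The endothelial-like share was 0% in DP 1 and 0% in DP 2 at resolution 0.5. It was also 0% and 0% with 1000 variable genes, where a cluster with 9 endothelial markers stayed unnamed by the rule on leading genes. Genes over 2-fold apart between the libraries numbered 1362 with the stricter filter and 949 in thinned cells, which test fewer genes.

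Called genes of the endothelial-marker class, 65 as reported, numbered 137 with no replicate block, 120 with robust fitting, 117 by the DESeq2 Wald test, 28 with looser marker numbers and 19 without the deepest cell of each class. Of these, 63, 65, 60, 24 and 17 were among the 65. For the neutrophil-marker class, with 95 called, the numbers were 150 with robust fitting, 220 in thinned cells, 235 by the DESeq2 Wald test and 33 without the deepest cell, of which 95, 73, 90 and 31 were shared. Genes tested numbered 6713 as reported, 1653 in thinned cells, 5491 without the deepest cell and 7426 with looser marker numbers, and 5537 and 3582 in the DESeq2 tests of the 2 classes. Without the library block the neutrophil-marker count was 119. The legacy method split the calls as 17 higher and 28 lower for the endothelial-marker class and 57 and 48 for the other.

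Called lists of the endothelial-marker class, 9 as reported, numbered 0 with an estimated correlation, 0 by directional fry, 3 by mixed fry and 4 in thinned cells. In thinned cells only 9 lists had enough genes, among them 5 of the 9, of which 3 stayed called. The arterial, basement membrane, Notch and junction lists were not tested there, and the fourth called list was the mitochondrially encoded one. For the neutrophil-marker class, with 3 called, they numbered 0 with an estimated correlation, 1 by directional and 1 by mixed fry, 6 with looser marker numbers and 7 with no count filter, where 18 and 24 lists were tested. The ribosomal list of the endothelial-marker class turned to the other side with adjusted p = 0.623 without the deepest cell and 0.840 in thinned cells, and over its alternatives the adjusted p ran from 8.52e-23 with no count filter to that value. Lists not called as reported were called in the same direction 4 times in the endothelial-marker class (G2/M and mitochondrially encoded genes) and 6 times in the other (hemogenic, ribosomal, G2/M and mitochondrially encoded genes). Only with alternatives were 3 further lists tested and called higher: epidermal (0.0421, no count filter) and mesenchymal genes (0.0169, looser marker numbers) in the first class and macrophage genes (0.0048, no count filter) in the second. With an estimated correlation in the same settings these were at 0.433, 0.323 and 0.714, and no list was called in any setting, with a lowest adjusted p of 0.0919.

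Lists not called as reported also turned to the other side, with the adjusted p given, and only ribosomal genes with no count filter and mitochondrially encoded genes with looser marker numbers, both in the neutrophil-marker class, were called there. In the endothelial-marker class these were mitochondrially encoded genes (0.901 with DESeq2 size factors, 0.264 without the deepest cell) and inflammatory genes (0.264 without the deepest cell, 0.840 in thinned cells). Skeletal muscle genes were on the other side by directional fry (0.865), which tests against no change and not against other genes. In the neutrophil-marker class, with no count filter, they were ribosomal (0.00167), G2/M (0.606), inflammatory (0.961), skeletal muscle (0.792), shear stress and BMP (0.976) and basement membrane genes (0.807). In thinned cells they were ribosomal (0.635), inflammatory (0.635) and shear stress and BMP genes (0.941), and without the deepest cell arterial (0.865) and basement membrane genes (0.865). Mitochondrially encoded genes turned with DESeq2 size factors (0.813), 2000 or more genes (0.943), without the deepest cell (0.859) and with looser marker numbers (0.0384), and Notch genes with 2000 or more genes (0.9998).

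Between the libraries the inflammatory median turned to -0.11, the mesenchymal one to -0.053 and the mitochondrially encoded one to 0.058 for means over cells, and the junction median to -0.0025 in thinned cells. Beyond the spread of random lists, the hemogenic median moved to -1.20 (percentile 1.16), the mitochondrially encoded one to -0.66 (0.00), the pan-myeloid one to -0.19, the neutrophil one to -0.61 and the G2/M one to -1.13 in thinned cells. For means over cells the neural median moved to 1.75, the neutrophil one to -0.57 and the immediate early and heat shock one to 0.30. The other 24 values stayed within that spread.

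Some named genes changed sign. Leaving out each library in turn gave -0.16 to 2.95 for spi2, -2.30 to 3.13 for cxcr4a, -0.15 to 0.73 for lmo2, -0.25 to 0.32 for cebpa, -2.58 to 2.11 for lfng, -0.31 to 0.91 for ctnnb1, -0.99 to 3.04 for lamb1a, -0.28 to 0.33 for id3, -0.92 to 0.89 for klf6a and -4.09 to 0.36 for id2a in the endothelial-marker class, and -2.04 to 0.021 for rpa2 in the other. In the endothelial-marker class cebpa was -0.062 with no block, -0.14 with no count filter, -0.18 with looser marker numbers and -0.026 with 2000 or more genes, and lfng was -0.15 without the deepest cell. There id3 was -0.18 with no count filter, -0.016 by the legacy method, -0.12 with looser marker numbers and -0.074 with 2000 or more genes. With DESeq2 size factors, the stricter filter, thinned cells and without the deepest cell, klf6a was 0.16, 0.031, 0.48 and 0.76. With no block, DESeq2 size factors, the stricter filter and thinned cells, id2a was 0.065, 0.23, 0.12 and 0.068. In the neutrophil-marker class cebpb was -0.074 with looser marker numbers.

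Of the other values for named genes, 718 kept direction and, where tested, side of the threshold in the endothelial-marker class. In that class 47 lost and 40 gained a call, and 493, 44 and 25 did so in the other. Of the 718, 65 left out DP 1 and 61 left out DP 2, and of the 493, 45 and 44 did. For these only the direction was compared, since they have no p-value. Of the values for lists, 93 kept direction and side of the threshold and 22 lost a call in the first class, and 99 and 5 did so in the second. Depth and 2 libraries limit what can be called: in simulated counts for the neutrophil-marker class 0.667% of genes changed 4-fold and 35.0% of those changed 64-fold were recovered, so a gene that was not called is not shown to be unchanged.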

Other observations

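All tests in this part were chosen after the results were seen. Transcripts of 1 embryonic globin gene were found in most DP cells. The gene hbae1.1 was found in 86.8% of DP 1 cells (46 of 53, interval 74.7 to 94.5) and 82.9% of DP 2 cells (29 of 35, interval 66.4 to 93.4), at 403 and 240 CPM. Its level in endothelial-marker cells, neutrophil-marker cells and cells of neither class was 538, 242 and 423 CPM in DP 1 and 77.1, 4.84 and 328 CPM in DP 2. The erythroid regulator genes gata1a and klf1 and the red cell anion exchanger gene slc4a1a had 0 counts in both libraries, which allows up to 0.325 CPM in DP 1 and 0.963 CPM in DP 2. Other genes of the erythroid list were found, such as the heme synthesis gene urod at 69.2 and 14.1 CPM and alas2 at 1.95 and 4.82 CPM, the latter in 1 cell of each library. The macrophage gene mpeg1.1 had 0 counts as well, and the lymphoid regulator gene ikzf1 was found in 92.5% of DP 1 cells and 65.7% of DP 2 cells.

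Immediate early and heat shock genes were higher in DP 2 summed over all cells, with a relative median of 3.46 for the 4 heat shock members and 1.18 for the 17 immediate early members. A few extreme cells do not account for the rise of the summed list, since the median cell was 2.13 times higher in DP 2 (10304 against 4827 CPM). Above the DP 1 median lay 80.0% of DP 2 cells. Immediate early members make up most of that sum, so it does not test the heat shock members alone. Of these, hsp70.1, hsp70.2, hsp70.3 and hsp70l were found in 69.0%, 75.9%, 72.4% and 89.7% of thinned DP 2 cells. In thinned DP 1 cells the shares were 12%, 18%, 24% and 48%. A different mix of marker classes does not account for the higher list in DP 2 either. The list median was 0.66 in cells of neither class, where the median gene was at -0.44. However, the rise was not found in endothelial-marker cells (list -0.20, median gene -0.40, percentile 44.4) or neutrophil-marker cells (0.046, 0.044, 54.6). A different mix of cells within the neither class was not tested. An unnamed cluster of 19 cells, 17 of them from DP 2, was led by cd59, csf3b and hsp70.1. A shift of the scaling by ribosomal genes points the other way. Their larger share of counts in DP 2 (40.8% against 30.9%) lowers the scaled level of other genes there. The list median of 1.23 relative to the median gene is therefore no further test of it. A difference between the libraries in handling, in batch or in the cells within the neither class may remain. Handling and batch cannot be separated from the library itself, and no biological explanation was tested.

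Neutrophil transcripts appeared in cells of neither class, with lyz at 532 CPM in DP 1 and 804 CPM in DP 2 against 22373 and 26008 CPM in neutrophil-marker cells. Carry-over of RNA from those cells alone would give each gene a like ratio of the 2 levels. Of 7 other genes of the neutrophil list, 5 lay over 2-fold below the ratio of lyz in both libraries by value. Of these 5, 3 (mpx, npsn and lect2l) had intervals that do not overlap that of lyz. The genes il6r and abcb9 lay over 2-fold above it. The 5 genes below do not decide the question, since all 7 are among the markers that define the classes. The lyz ratio also rests on few cells: the 3 highest cells of neither class held 73.0% of that class's lyz counts in DP 1 and 93.3% in DP 2. The 3 cells of neither class with over 1000 lyz counts held 0.365 npsn counts per 100 lyz counts (interval 0.204 to 0.603), but the neutrophil-marker cells of DP 2 held 1.18 and 28.3 and those of DP 1 from 13.0 to 27.8, so missed neutrophils with little npsn stay open for these 3 cells. Without them, lyz stood at 0.783% and 0.443% of its level in neutrophil-marker cells and npsn at 0.464% and 0.420%, and 2 of the 7 genes, il6r (47.2% and 12.7%) and abcb9 (4.87% and 8.65%), lay over 2-fold above lyz in both libraries. In endothelial-marker cells il6r was at 405 CPM in DP 1 and 6.22 CPM in DP 2. Carry-over from the neutrophil-marker cells therefore stays open for the low level of the other genes, but not as the only source of il6r and abcb9. No biological explanation was tested.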
